A study of Bradyrhizobium diazoefficiens USDA 110 with 46 samples.

How the data were processed

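The series measured transcript ratios in Bradyrhizobium diazoefficiens USDA 110, a nitrogen-fixing soybean symbiont, with 46 arrays in 2 colours. Bacteroids, the form the bacterium takes inside root nodules, were harvested from soybean plants 34, 43, 49, 55, 71 or 95 days old and compared on every array with free-living bacteria from cultures in HM medium with arabinose that were 4 weeks old. Per the labels' protocols, total RNA was extracted with hot phenol, copied to cDNA with random hexamers and labelled with Cy3 or Cy5. Each age had 4 independent biological materials per the series' design text, giving 24 replicates. Each replicate had a forward array and a dye swap, except replicate 4 at 34 d (dye swap only) and replicate 3 at 55 d (forward only), so there were 23 forward and 23 dye-swap arrays, 7 or 8 per age.

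The values are those of 1 deposited table of processed ratios, in which the authors give 1 value per table row and array. Scanner files were not used here, so background correction, spot filters and signal over background were not examined, and the normalization and its tools are not given in the sources used here. The deposited values were read as log2 ratios from their range of -8.84 to 9.83 and their array medians of -0.0785 to 0.0703. The base of the logarithm is not stated, so all values are log2 on that reading only. Adjusted p-values and counts at an adjusted p alone do not depend on the base, while counts at an absolute log2 value of at least 1 do. The direction, bacteroids over free-living cells, comes from the ratio each array's label names. Dye-swap arrays correlated positively with the forward array of the same replicate (mean r = 0.598 across genes, which are not independent replicates). The table was therefore taken as already turned, and no sign was changed. No pair of arrays held identical values, a count of 0 pairs.

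Of 8480 rows, 7619 had a value on all 46 arrays and 861 on none. Of these valued rows, 16 had no entry in the probe annotation and were left out. The annotation gave 1 gene name to each of 8462 probes and several to 0. It left 7426 genes by locus tag, 159 of them with several rows, which were averaged per array. A symbol was given for 1332 genes, and 6094 were known by locus tag only. No gene products were used, because 0 of the tags matched the RefSeq gene table, so no genome coordinates are given either. The number of arrays, not a read depth, limits the precision.

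Each array was centred on its median over all genes, and the forward and dye-swap values of a replicate were averaged. The 24 replicate values per gene were fitted with limma 3.58.1 in R 4.3.3 as 6 age means. Tests followed of each age against 0, of the mean over ages against 0, of 95 d against 34 d, of each step between successive ages, and of any difference among ages (F-test). Moderated p-values (eBayes) were adjusted with Benjamini-Hochberg over all genes, and an adjusted p under 0.05 counted as past the threshold. The estimated prior degrees of freedom were infinite, so every gene shared an SD of 0.851. Standard errors were therefore 0.174 for a mean over ages and 0.602 for a difference between ages. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

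Before the data were examined, 32 gene lists were fixed. They were matched by symbol or locus tag, and 27 held at least 5 genes and were tested with camera at a preset correlation of 0.01 for the mean over ages and for 95 d against 34 d. An estimated correlation was the alternative. The tested lists were nitrogenase, fix electron transfer and cbb3 oxidase, oxygen and nitrogen-fixation regulators, uptake hydrogenase, denitrification, nodulation, type III secretion, flagella and chemotaxis, ribosomal proteins, aminoacyl-tRNA synthetases, ATP synthase, NADH dehydrogenase complex I, other cytochrome oxidases and bc1, tricarboxylic acid cycle, C4-dicarboxylate uptake, Calvin cycle, polyhydroxybutyrate, trehalose and glycogen, heat shock and chaperones, ammonium assimilation, iron uptake and heme, amino acid biosynthesis, cell division and peptidoglycan, proteases, sigma factors, exopolysaccharide, and the nod-nif chromosomal window of locus tags. The lists for oxidative stress, pentose catabolism, and hopanoid and carotenoid held 3, 2 and 1 genes and were not tested as lists. A further 2 lists, for ABC transporters and transposases, need product names and were not matched. Symbols for the tricarboxylic acid cycle and the synthetases were chosen after the files were seen, before their values. Matching by prefix has faults: the amino acid list holds some tRNA synthetases (94 genes, 85 without them), the hydrogenase list takes hup and hupA, the ammonium list takes gltA, gltX, gltI and gltP, and the flagellin genes fla and flaA are not in the flagella list.

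The rule for named genes was also fixed before the data were examined. It takes nifH, nifD, nifK, nifA, fixN, fixK2 (listed here as fixK), nodA, and every groEL and dctA. For the mean over ages it takes the 10 highest and 10 lowest genes past the threshold with 1 sign in every replicate. For 95 d against 34 d it takes the 10 highest and 10 lowest past the threshold with no overlap between the ages, and for each step the 3 highest and 3 lowest past the threshold. From each list it takes the 2 members past the threshold with the largest size in each of the 2 comparisons, and from the F-test the 5 smallest p. Among genes without a product only the most extreme 1 in each direction was to be named. With no products at hand, a gene with a symbol was treated as annotated. The rule named 130 genes, not all of which are printed. Named besides, after their values were seen, are members of a list behind a count of 5 or fewer past the threshold over all genes, and the nitrogenase and hydrogenase genes lower at 95 d.

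Alternatives fixed beforehand were no centring, scaling to one median absolute deviation, quantile normalization, a fit of all arrays with a dye term and the extract pair as a random block, forward arrays only, dye-swap arrays only, leaving out the replicates with 1 array, the replicate number as a block, genes with a value in every replicate or in at least 2 of 4, the median of a gene's rows, eBayes with trend and robust, a fit of only the ages compared, an adjusted p under 0.01, an absolute log2 value of at least 1, and leaving out each replicate. The labels do not state whether same-numbered replicates are paired, so the block is not part of the tests.

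After the data were seen, a further alternative was added. Deviations from each row's mean over arrays repeated along the rows of the table, with 1 turn in about 48 rows, and their phase differed between arrays. This row-position component was removed by centring each array's deviations on their median within 96 classes of row, each class set from the 4 neighbouring rows on each side. It was also combined with the replicate block and with the estimated correlation.

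The tests were tested on simulated data. With values drawn for 95 d against 34 d on 7426 genes, 1% of genes changed by a log2 of 1 and 27% of those changed by a log2 of 2 were recovered, and 1 of 29 calls was on an unchanged gene. For the mean over ages, on 7374 genes, these shares were 94.8% and 100%, with 12 of 218 calls on unchanged genes. The F-test, on 7426 genes, recovered 23% of genes changed by a log2 of 2 at 1 age. With a simulated row-position component on 7619 rows, 95 d against 34 d recovered 0% and 1% with the component left in, and 41% and 84% with it removed, with 8 of 133 calls on unchanged rows. That simulated component repeated at an exact period and turned by fixed steps between arrays, more regularly than the one in the data. These shares therefore do not measure recovery in the data themselves. In the simulation of 28 lists the shifted list was called and 0 others were. Genes were drawn independently of each other there, so it cannot show how often lists are called falsely when their genes vary together.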

Results

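Transcript ratios of Bradyrhizobium diazoefficiens bacteroids to free-living cells were obtained for 7426 genes on 46 arrays. The soybean plants were 34, 43, 49, 55, 71 or 95 days old, with 4 biological replicates at each age. All values are centred ratios read as log2, so a gene is higher or lower relative to the median gene of its array. The nitrogenase genes gave a check of direction. The ratio of nifH, which encodes the iron protein of nitrogenase, was above 0 on 23 of 23 forward and 23 of 23 dye-swap arrays, with means of 4.85 and 6.49. Those of nifD and nifK, for the subunits of the molybdenum-iron protein, were also above 0 on all of them, with forward and dye-swap means of 4.65 and 5.84 for nifD and 4.70 and 5.08 for nifK.

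Replicates of one age correlated with r between 0.512 and 0.811 across genes. On each array, neighbouring rows of the value table deviated together from their means over arrays, in a pattern that repeated along the table and differed in phase between arrays. This row-position component held 52.6% of the variance between arrays. Before its removal the most similar array came from the same plant age for 2 of 46 arrays, and after it for 44. An array's own dye swap was its most similar array for 0 of 46 before the removal and 3 after it. As centred, the 2 arrays of an extract pair had a correlation beyond their shared age of 0.110, estimated with limma. Arrays of a replicate were thus little more alike than other arrays of that age. Counts are given below as centred, and with the component removed where that moved them by over 1.5 times.

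The comparison of bacteroids with free-living cells over all ages asked which genes differ between bacteroids and this one reference. All free-living cells came from cultures 4 weeks old in HM medium with arabinose. Effects of culture age or medium therefore cannot be told apart from those of symbiosis. Most nitrogenase genes were high in bacteroids. Over 24 replicates (SE 0.174 for every gene), nifH had a mean log2 ratio of 5.66 ± 1.43 (SD, n = 24), nifD 5.24 ± 1.07, nifK 4.94 ± 1.40 and nifB, for synthesis of the nitrogenase cofactor, 4.83 ± 1.30. Of 14 nitrogenase genes 12 rose and 2 fell, both nifS copies outside the symbiotic region (blr4338 -0.98 and blr4342 -1.40), and the list was higher than other genes with a median of 4.20 (limma's camera, adjusted p = 9.17e-26, and 8.15e-05 with an estimated correlation). Their activator nifA rose by 3.05. The list p-values here and below carry a limit, since 15 of 100 sign patterns of the replicates, the real one included, called as many lists. Other high genes with 1 sign in 24 of 24 replicates were ahpC, for a peroxide-reducing enzyme (5.25), nrgC (5.24), the cytochrome P450 genes CYP112 (5.20) and CYP114 (4.78), and phoD (4.99). The highest gene known by tag only was blr6123 at 7.05.

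Most ribosomal protein genes and most flagella and chemotaxis genes were lower in bacteroids. Of the 52 genes listed as ribosomal proteins 51 were lower in bacteroids and 0 higher, with a median of -2.12 (adjusted p = 9.17e-26, and 0.000242 with an estimated correlation). Ribosomal genes rplE and rpsC stood at -3.76 and -3.61. Among 50 flagella and chemotaxis genes 39 fell and 2 rose, with a median of -1.04 (adjusted p = 1.23e-11, and 0.000304 with an estimated correlation). Flagellar flgL and flgB were each at -3.78, and the flagellin gene fla at -3.90. Other low genes, below 0 in every replicate, were nirK, for copper nitrite reductase (-4.87 ± 1.69, SD, n = 24), mntH, for a manganese transporter (-4.63 ± 0.80), tspO (-3.89) and norC, for a nitric oxide reductase subunit (-3.67). The lowest gene known by tag only was bll5085 at -5.23.

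Denitrification, complex I and ATP synthase genes were lower by the preset test, but not with an estimated correlation. In the denitrification list 14 of 17 genes fell and 1 rose, with a median of -1.12 (adjusted p = 4.26e-05, but adjusted p = 0.0678 with an estimated correlation). In NADH dehydrogenase complex I 9 of 13 fell and 2 rose, and nuoL and nuoM were at -3.37 and -3.22 (adjusted p = 0.000172, but adjusted p = 0.285 with an estimated correlation). In ATP synthase 7 of 8 fell and 0 rose, with atpC at -3.12 (adjusted p = 0.00347, but adjusted p = 0.108 with an estimated correlation, and 0.0410 with that and the row-position component removed). Going the other way, in the list for trehalose and glycogen 7 of 8 rose, and otsA, for trehalose-6-phosphate synthase, was at 3.37 (adjusted p = 0.0326, but adjusted p = 0.0678 with an estimated correlation). In the nod-nif chromosomal window, the stretch of locus tags that holds most symbiosis genes, 271 of 527 genes rose and 115 fell, with a median of 0.39 (adjusted p = 1.13e-10, and 2.15e-06 with an estimated correlation). The highest of them by tag only was blr1726 at 5.26. Adjusted over the list alone, the counts were 272 and 117 for the window and unchanged for the other 7 of these 8 lists.

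The other 19 lists did not pass. With the row-position component removed, amino acid biosynthesis (adjusted p = 0.00631), aminoacyl-tRNA synthetases (0.0227) and iron uptake and heme (0.0393) did. With an estimated correlation as well, the adjusted p of these lists was 0.0410, 0.0444 and 0.0590. Of the genes named beforehand, 4 of 7 dctA genes, for C4-dicarboxylate transporters, rose, bll1718 at 2.45, blr3840 at 1.69, blr3723 at 1.08 and blr6145 at 0.47. The C4-dicarboxylate list had adjusted p = 0.157. Of 4 groEL chaperonin genes bll2059 (3.73) and blr5227 (0.57) rose and blr5626 (-3.29) and blr7533 (-2.94) fell, and 18 of 26 heat shock and chaperone genes rose and 6 fell (adjusted p = 0.268). Of 5 fixK genes, which encode regulators of the oxygen response, bll3466 rose by 3.53 while bll2757, the gene of the fixK2 regulator, stood at -3.15, bll7696 at -2.31 and bll2109 at -1.99. The remaining fixK gene, bll6061, was at -0.37 (adjusted p = 0.0486), a call lost without any 1 of 15 of the 24 replicates. The regulator list had 6 of 17 genes higher and 9 lower (adjusted p = 1). The oxidase gene fixN was at 0.17 (adjusted p = 0.378) while fixX, for a ferredoxin-like protein of the same fix list, rose by 3.94. That list had 4 of 13 higher, with fixC (3.47), fixB (2.05) and fixA (1.24), and 7 lower (adjusted p = 1). The gene nodA, for an acyltransferase of Nod factor synthesis, fell by 0.83, in a nodulation list with 16 of 32 higher and 8 lower (adjusted p = 0.801).

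In the uptake hydrogenase list 17 of 36 genes rose, among them hupG (3.69) and hupH (3.62), and 7 fell (adjusted p = 0.15). Higher and lower numbers in the others were 18 and 47 of 94 for amino acid biosynthesis (adjusted p = 0.0768), 1 and 11 of 19 for aminoacyl-tRNA synthetases (0.157), 3 and 10 of 19 for iron uptake and heme (0.197), 4 and 0 of 7 for sigma factors (0.197) with rpoN2 at 2.90, and 7 and 0 of 9 for the Calvin cycle (0.268). They were 0 and 4 of 7 for type III secretion (adjusted p = 0.279), 3 and 8 of 20 for cell division and peptidoglycan (0.305), 2 and 4 of 7 for exopolysaccharide (0.539), 2 and 7 of 12 for the tricarboxylic acid cycle (0.65) and 4 and 2 of 9 for proteases (0.786). The last were 5 and 7 of 22 for ammonium assimilation (adjusted p = 0.857), with glnK blr0612 at 2.65 and glnA blr4949 at -1.92, 5 and 4 of 16 for other cytochrome oxidases and bc1 (1), and 1 and 1 of 5 for polyhydroxybutyrate (1). Adjusted over the list alone, the counts of higher and lower genes became 2 and 11 for the synthetases, 3 and 11 for iron uptake and heme, 16 and 9 for nodulation and 1 and 0 for polyhydroxybutyrate, and the other 15 lists kept theirs. Median and mean differed in sign for the fix list (-0.66 and 0.01, test lower), the other cytochrome oxidases (-0.15 and 0.01, lower), the regulators (-0.37 and 0.02, higher) and polyhydroxybutyrate (-0.22 and 0.00, lower). Of the untested lists, 3 of 3 oxidative stress genes rose with a median of 2.71, the hopanoid gene shc rose by 1.28, and 0 of 2 pentose catabolism genes passed in limma, with 0 at an unadjusted p under 0.05.

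Behind the small counts of these lists, the higher genes were nuoE (1.33) and nuoF (1.28) of complex I, fliX (1.10) and flgE (0.52) of the flagella list, nosR (0.49) of denitrification. They were also glyQ (0.79) of the synthetases and hmuR (1.76), tonB (0.82) and exbD (0.62) of iron uptake. Higher sigma factor genes were rpoN2, rpoH1 (1.14), rpoN1 (0.97) and rpoH3 (0.54). Further such genes were ftsJ (1.34), ftsZ (0.73) and ftsA (0.53) of cell division, fumC bll0286 and blr6519 (each 0.63) of the tricarboxylic acid cycle, and sodF (1.44) with ahpC and ahpD of oxidative stress. In ammonium assimilation glnII (1.40), amtB (1.09), glnA blr4835 (0.87) and glnK blr0606 (0.43) rose besides glnK blr0612. The lower type III secretion genes were rhcS (-1.23), rhcV (-1.03), rhcQ (-0.96) and rhcR (-0.82). For exopolysaccharide exoM (0.43) and exoZ (0.39) were higher and exoU (-1.40), pssA (-1.20), exoT (-0.50) and exoB (-0.37) lower. Among proteases lon (1.31), hslU (1.16), hslV (0.74) and clpP blr0611 (0.70) were higher and clpP bll4944 (-1.20) and clpX (-0.45) lower. Other oxidase genes were cyoA (1.57), cyoC (1.03), coxM (0.80), coxC (0.72) and cyoD (0.49), higher, and coxG (-1.5), coxE (-1.08), coxB (-0.80) and coxA (-0.45), lower. For polyhydroxybutyrate phbB blr3725 (0.80) was higher and phbA (-0.37, adjusted p = 0.0499) lower. Calls were lost for glnK blr0606 without 49 d replicate 4 (0.38), exoM without 55 d replicate 2 (0.38) or 95 d replicate 4 (0.38), coxA without 43 d replicate 1 (-0.38) or 71 d replicate 3 (-0.38), and clpX without 71 d replicate 4 (-0.38). That on exoZ was lost without 34 d replicate 4, 43 d replicates 2 or 4, 49 d replicates 1 or 3, 55 d replicate 1, 71 d replicates 2 or 3 or 95 d replicate 3 (0.31 to 0.38). The call on exoB was lost without 34 d replicates 1 or 2, 43 d replicates 1 or 3, any 1 of the 4 replicates at 49 d, 55 d replicates 1 or 2, 71 d replicates 2 or 3 or 95 d replicates 1 or 3 (from -0.38 to -0.29). For phbA it was lost without 34 d replicates 1 or 3, 43 d replicates 2 or 3, 49 d replicates 1, 3 or 4, 55 d replicates 1 or 3, 71 d replicates 2, 3 or 4 or 95 d replicates 3 or 4 (from -0.38 to -0.30).

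In all, 4754 of 7426 genes passed, 2426 higher and 2328 lower, and 925 of the higher and 1033 of the lower had an absolute log2 value of at least 1. The sign was the same in every replicate for 286 of the higher and 458 of the lower. Removing the row-position component gave 6099 genes, 4714 of them shared with the 4754. The removal acts on deviations from each row's mean over arrays, so it leaves the mean over ages nearly unchanged by construction. The sharing is therefore no check on these ratios. Row-position classes held 5.92% of the variance of the mean over ages before the removal and 6.09% after it, against 1.24% with classes shuffled. A part of the component thus stays in these means, while the removal lowered the prior SD from 0.851 to 0.320. The 6099 may therefore include genes called for that part alone.

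**Figure D1:**
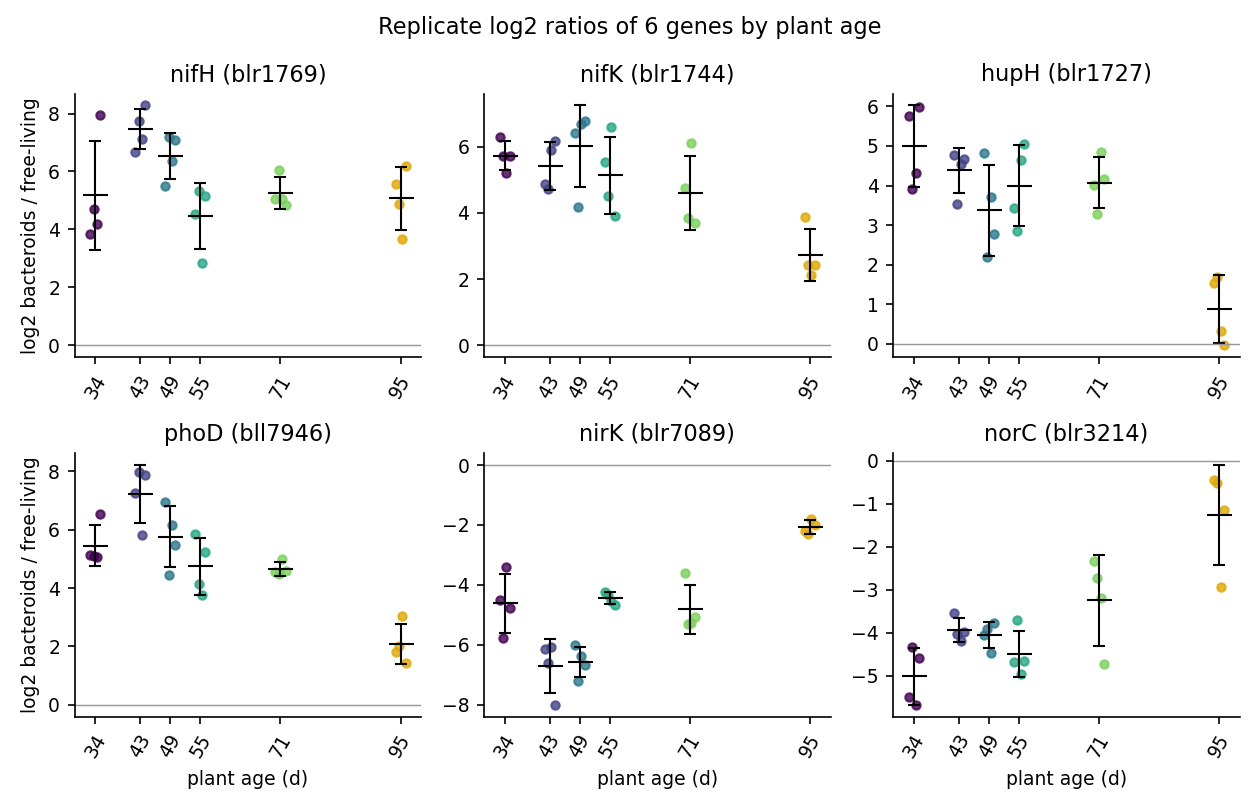
Log2 ratio of bacteroids to free-living cells (vertical axis) against plant age in days (horizontal axis) for 6 named genes, with a point for each of the 4 replicates, a horizontal bar for their mean and error bars of 1 SD. At 95 d nifK stood at 2.72 and nirK at -2.08, against 5.74 and -4.62 at 34 d.

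Against free-living cells at single ages, nifH ranged from 4.46 ± 1.14 (SD, n = 4) at 55 d to 7.46 ± 0.70 at 43 d and nifD from 4.35 ± 1.19 at 95 d to 6.07 ± 0.25 at 34 d. The groEL gene bll2059 was at 5.30 ± 0.53 at 43 d and at 1.13 ± 0.09 at 95 d. The nitrite reductase gene nirK lay at -6.70 ± 0.90 at 43 d and at -2.08 ± 0.23 at 95 d. Higher and lower genes numbered 1247 and 1295 at 34 d, 1227 and 1170 at 43 d, 1301 and 1237 at 49 d, 999 and 1157 at 55 d, 977 and 1059 at 71 d, and 1121 and 1337 at 95 d. With the row-position component removed the totals were 4830, 4575, 4708, 4502, 4304 and 4630, against 2542, 2397, 2538, 2156, 2036 and 2458 as centred. These larger totals may be inflated, since each row's mean over arrays keeps its part of the component in the ratio at every age.

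Differences among ages were tested for any gene with an F-test. The 5 genes of smallest p were blr4599, between 0.63 ± 0.59 (SD, n = 4) at 55 d and 5.50 ± 1.19 at 49 d, mdcE, for a malonate decarboxylase subunit, between -0.33 ± 0.63 at 43 d and 4.92 ± 1.33 at 34 d, hypA, for hydrogenase maturation, between -0.10 ± 0.89 at 71 d and 4.06 ± 1.53 at 49 d, phoD, between 2.07 ± 0.68 at 95 d and 7.22 ± 0.99 at 43 d, and nirK. Adjusted p ran from 2.19e-17 for blr4599 to 7.87e-13 for nirK. In total 1306 genes differed among ages, and 4571 with the row-position component removed, 1234 of them shared.

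Between 34 and 95 d a part of the nitrogenase genes fell. The differences were -3.02 for nifK (SE 0.602 for every gene, n = 4 and 4, adjusted p = 6.27e-05), -2.90 for nifN, -2.88 for nifW, -2.84 for nifE, -2.43 for nifX, -2.39 for nifB and -2.29 for nifQ. Thus 7 of 14 nitrogenase genes fell and 0 rose, 10 adjusted over the list alone, with a list median of -2.01 (camera, adjusted p = 5.58e-10, and 0.0152 with an estimated correlation). The difference was not past the threshold for nifD (-1.72, adjusted p = 0.067), nifA (-1.19, adjusted p = 0.299) or nifH (-0.10, adjusted p = 0.962). With the row-position component removed nifD (-1.13, adjusted p = 0.0262) and nifA (-1.94, adjusted p = 5.63e-10) passed. The replicate block (-1.72) or leaving out 95 d replicate 1 (-2.13) also put nifD past it. The call on nifQ was lost without 34 d replicate 2 (-1.86) or 95 d replicate 3 (-1.81). The sign for nifH turned under quantile normalization (1.01), scaling to one median absolute deviation (0.033), the dye-term fit (0.38), forward arrays only (1.93), without the replicates of 1 array or 34 d replicate 4 (0.83) and without 95 d replicate 3 (0.37).

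In the nod-nif chromosomal window 111 of 527 genes fell and 5 rose, 134 and 11 adjusted over the list alone, with a median of -0.56 (adjusted p = 1.57e-11, and 7.83e-07 with an estimated correlation). Its most lowered gene by tag was blr1851 at -4.31. Among genes with a symbol, the lowest past the threshold with no overlap between the ages were mdcE (-4.23, adjusted p = 3.14e-09), hupH (-4.10), pstB, for the ATPase of a phosphate transporter (-3.58), phoD (-3.38), modB, for a molybdate transporter (-3.16), hypD (-3.13), the ferredoxin gene fer3 (-3.10), fixX (-3.05) and hypA (-3.03). The lowest such gene known by tag only was bll5076 (-4.62), and others by tag only are not ranked here. Of the nodulation list nolZ (-3.01), nolY (-2.77), nolA (-2.33) and nodY (-2.15) fell and the regulator gene nwsA (1.91) rose, and ahpC and ahpD each fell by 2.81. The call on nolA was lost without 34 d replicate 3 (-1.75), that on nodY without 34 d replicate 4 (-1.87) or 95 d replicate 2 (-1.90) or 4 (-1.94). For nwsA it was lost without 34 d replicates 1 or 3 or any 1 of the 4 replicates at 95 d (1.63 to 2.01). The 5 window genes that rose were blr1817 and blr2123 (each 2.20), bsl1808 (1.96), bsr1607 (1.94) and bsl1772 (1.87). The call on blr1817 was lost without 34 d replicate 2 (1.79) or 95 d replicate 4 (1.99). For blr2123 this was so without 34 d replicate 4 (1.56) or 95 d replicate 3 (1.98). The gene bsl1808 lost its call without 34 d replicates 1 or 4 or 95 d replicates 3 or 4 (1.61 to 2.01). So did bsr1607 without 34 d replicates 1 or 3 or 95 d replicates 1, 2 or 4 (1.65 to 1.95), and bsl1772 without 34 d replicates 1 or 4 or 95 d replicates 1 or 3 (1.21 to 1.97). With the component removed blr2123 (1.31, adjusted p = 0.0778), bsl1772 (0.74, adjusted p = 0.183) and bsl1808 (0.64, adjusted p = 0.268) did not pass, and bsr1607 was at 1.19, nodY at -1.05 and hypD at -2.02.

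Genes that rose toward 95 d included norC (3.75, adjusted p = 2.56e-07) and nirK (2.55, adjusted p = 0.00115), which stayed below free-living cells at -1.26 ± 1.16 (SD, n = 4) and -2.08 ± 0.23. The small heat-shock genes hspB and hspE rose by 2.62 and 2.61, the periplasmic protease gene degP by 2.35, the flagellar ring gene flgI by 3.06, fixK bll2757 by 2.39 and bsl7085, known by tag only, by 3.72. The chaperonin genes past the threshold, in a list that did not pass, were groES bll2060 at -2.76, groES blr6978 at -2.73, groES blr5226 at -2.0 and groEL bll2059 at -2.14. The call on groEL bll2059 was lost without 34 d replicate 1 (-1.86), and that on groES blr5226 without 34 d replicate 2 (-1.80) or 4 (-1.83) or 95 d replicate 1 (-1.25) and with the component removed (-2.06, adjusted p = 0.154). Without 34 d replicate 4 groEL blr5626, at -1.58, passed as well (-2.05). The rule also took cycH, for cytochrome c biogenesis (2.00, adjusted p = 0.0227), and trbD, for conjugal transfer (2.06, adjusted p = 0.0169). The call on cycH was lost without 34 d replicate 1 (1.87) or 4 (1.73) or 95 d replicate 3 (1.74) or 4 (1.92), and that on trbD without 34 d replicate 1 (1.98) or 4 (1.49) or 95 d replicate 3 (1.83) and with the component removed (1.63, adjusted p = 0.0697). That removal also brought degP to 1.03, cycH to 0.68 and hspB to 1.73.

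Further lists passed by the preset test alone. In the uptake hydrogenase list 7 of 36 fell and 0 rose, with the large and small subunit genes hupL and hupS at -1.96 and -2.42, hupK at -2.74 and hypE at -1.93 besides those above (adjusted p = 0.00194, but adjusted p = 0.202 with an estimated correlation). The call on hupS was lost without 34 d replicate 4 (-1.78), that on hupL without 34 d replicate 2 or 95 d replicates 1, 2 or 3 (from -1.92 to -1.46) and that on hypE without 34 d replicates 1, 3 or 4 or 95 d replicates 2 or 4 (from -1.98 to -1.42). Among ribosomal proteins 2 of 52 fell, rpsJ (-1.92) and rpsQ (-1.91), 5 adjusted over the list alone, with a median of -0.60 (adjusted p = 0.00932, but adjusted p = 0.413 with an estimated correlation). The list lost its call without 34 d replicate 2 (adjusted p = 0.0557) or 95 d replicate 3 (0.0709). In the list for fix electron transfer and cbb3 oxidase 3 of 13 fell, fixX, fixB (-2.85) and fixC (-2.72) (adjusted p = 0.024, but adjusted p = 0.413 with an estimated correlation, 0.107 without 34 d replicate 2, 0.135 without 95 d replicate 1 0.0709 without 95 d replicate 3 and 0.0742 on forward arrays). In the denitrification list 3 of 17 rose, norC, nirK and norD (1.92) (adjusted p = 0.0283, but adjusted p = 0.413 with an estimated correlation, 0.0668 with the row-position component removed, 0.0966 on dye-swap arrays, and 0.0609, 0.197, 0.0757 and 0.0738 without 34 d replicates 1, 2 and 3 and 95 d replicate 1). In NADH dehydrogenase complex I 1 of 13 fell, nuoE (-1.86), and 2 adjusted over the list alone (adjusted p = 0.0379, but adjusted p = 0.708 with an estimated correlation, 0.109 on dye-swap arrays, and 0.316, 0.0608, 0.065 and 0.513 without 34 d replicates 2, 3 and 4 and 95 d replicate 1). The call on norD was lost without 34 d replicates 1 or 3 or 95 d replicates 2 or 4 (1.45 to 1.97), and that on rpsJ without 34 d replicates 1 or 4 or 95 d replicates 1, 2 or 3 (from -1.98 to -1.74). The call on rpsQ was lost without 34 d replicates 1, 2 or 3 or 95 d replicates 1 or 3 (from -1.94 to -1.41), and that on nuoE without 34 d replicates 2 or 4 or 95 d replicates 1, 3 or 4 (from -1.86 to -1.56).

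The other 20 lists did not pass. Those with members past the threshold, given as higher and lower, were C4-dicarboxylate uptake (0 and 1 of 7, adjusted p = 0.225), where dctA bll1718 was at -2.01, flagella and chemotaxis (2 and 0 of 50, 0.116, but 0.0241 on forward arrays) with flgI and flgH (1.92), ammonium assimilation (0 and 2 of 22, 0 and 3 adjusted over the list alone, 0.18) with gltB (-2.13) and glnK blr0606 (-1.96), trehalose and glycogen (0 and 1 of 8, 0.419) with otsA falling by 2.41, nodulation (1 and 4 of 32, 0.587), polyhydroxybutyrate (1 and 0 of 5, 0.607) with phbB bll0225 at 1.97, regulators (1 and 0 of 17, 0.917), heat shock and chaperones (2 and 4 of 26, 2 and 5 over the list alone, 0.933), proteases (1 and 0 of 9, 0.933), the tricarboxylic acid cycle (0 and 1 of 12, 1 and 1 over the list alone, 0.977) with sdhB at -2.10, and amino acid biosynthesis (1 and 3 of 94, 0.982) with ilvE bll0229 (1.94), dapB blr0685 (-1.90), lysC (-1.90) and ilvI bll6503 (-1.87). The call on dctA bll1718 was lost without 34 d replicate 2 (-1.81) or 4 (-1.81) or 95 d replicate 1 (-1.76) or 3 (-1.80), and that on sdhB without 34 d replicate 4 (-1.71) or 95 d replicate 4 (-2.01). Calls were also lost for flgH without 34 d replicates 3 or 4 or 95 d replicates 1, 3 or 4 (1.48 to 1.96) and gltB without 34 d replicate 1 (-1.82) or 95 d replicate 4 (-1.71). The same held for glnK blr0606 without 34 d replicates 1, 2 or 4 or 95 d replicates 1 or 3 (from -1.89 to -1.69), and phbB without 34 d replicate 4 or 95 d replicates 1, 3 or 4 (1.23 to 2.01). Of the amino acid genes, ilvE lost its call without 34 d replicates 1 or 4 or 95 d replicates 1 or 3 (1.49 to 1.89) and dapB without 34 d replicates 2 or 4 or 95 d replicates 2 or 3 (from -1.85 to -1.46). Likewise lysC lost its call without 34 d replicates 1, 2 or 3 or 95 d replicates 2, 3 or 4 (from -1.90 to -1.63), and ilvI without 34 d replicates 1 or 4 or 95 d replicates 2 or 4 (from -1.98 to -1.42). With the component removed phbB was at 0.64, lysC at -1.03 and otsA at -1.55. Lists with 0 members past the threshold in limma, each with the adjusted p of the list and its members at an unadjusted p under 0.05, were ATP synthase (0.0527, 2 of 8), type III secretion (0.419, 0 of 7), aminoacyl-tRNA synthetases (0.917, 2 of 19), cell division and peptidoglycan (0.917, 1 of 20), iron uptake and heme (0.933, 2 of 19), sigma factors (0.933, 1 of 7), the Calvin cycle (0.977, 2 of 9), other cytochrome oxidases and bc1 (0.977, 3 of 16) and exopolysaccharide (0.982, 1 of 7). ATP synthase passed without 34 d replicate 2 (adjusted p = 0.0407) or 4 (0.0496) or 95 d replicate 3 (0.0134), with the row-position component removed (0.0442), with one median absolute deviation (0.0379) and on dye-swap arrays (0.0246), but not with an estimated correlation (0.413). Adjusted over the list alone, 1 sigma factor gene was lower. Median, mean and test differed in sign for the Calvin cycle (-0.55, -0.01, higher), exopolysaccharide (0.34, -0.07, lower), heat shock (0.01, -0.15, lower), iron uptake (-0.01, 0.01, higher), other cytochrome oxidases (-0.09, -0.04, higher), sigma factors (0.11, -0.17, lower) and the tricarboxylic acid cycle (0.14, -0.11, lower). Of the untested lists, 2 of 3 oxidative stress genes fell, and 0 of 2 pentose genes and 0 of 1 hopanoid gene passed, with 1 hopanoid gene lower over the list alone.

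Of 404 genes that differed between 95 and 34 d, 93 were higher and 311 lower. Over all genes the replicates of the ages did not overlap for 224 with the later age higher and 419 with it lower, or 8.66% of 7426, where chance gives 2.86%. The row-position component held 23.7% of the variance of this difference across genes. With it removed 2091 genes passed, 802 higher and 1289 lower, 377 of them shared with the 404. The gene nodA was at -0.08 (adjusted p = 0.97) as centred and at 1.07 (adjusted p = 0.0156) with the component removed.

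From 34 to 43 d the largest fall was that of mdcE, from 4.92 ± 1.33 to -0.33 ± 0.63 (SD, n = 4 and 4; difference -5.25, SE 0.602, adjusted p = 2.01e-14). The small heat-shock gene hspF fell by 3.02 and bll6324 by 3.81. Genes that rose were phnJ, for phosphonate breakdown (3.19), rpmJ, for a ribosomal protein (2.78), and bll5888 (3.30, and 1.78 with the row-position component removed). In all 227 genes rose and 203 fell. Over all 7426 genes the ages did not overlap for 416 higher and 254 lower, or 9.02%, where chance gives 2.86%. The total of 430 was 212 without 34 d replicate 1, 181 without 34 d replicate 3, 201 without 43 d replicate 1 and 206 without 43 d replicate 2. It was 2063 (1106 higher and 957 lower) with the row-position component removed, which held 41.0% of the variance of this difference, and 366 of those were shared.

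From 43 to 49 d few genes passed. The highest by tag was blr4599, which rose by 3.13 (SE 0.602, adjusted p = 0.0015), and hypE, for hydrogenase maturation, rose by 2.43 (adjusted p = 0.0372, and by 1.61 with the row-position component removed). The only gene that fell was blr2571 (-2.51, adjusted p = 0.0372). The call on hypE was lost without 43 d replicate 1 (1.75) or 2 (2.20) or 49 d replicate 1 (2.40), 3 (2.11) or 4 (2.41), and that on blr2571 without 43 d replicates 1, 2 or 3 or 49 d replicates 1, 2 or 4 (from -2.60 to -2.20). In all 11 genes rose and 1 fell. Over all genes there was no overlap for 73 higher and 202 lower, or 3.70%, where chance gives 2.86%. The total of 12 was 3, 3, 2 and 6 without 43 d replicates 1 to 4 and 2, 4, 6 and 5 without 49 d replicates 1 to 4. It was 468 (293 higher and 175 lower) with the row-position component removed, which held 43.7% of the variance of this difference, and 12 of those were shared.

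From 49 to 55 d hypA fell by 3.82 (SE 0.602, n = 4 and 4, adjusted p = 1.99e-07), pepA, for an aminopeptidase, was at -3.86 and blr4599 at -4.86. Genes that rose were the cold-shock gene cspA (2.72, adjusted p = 0.000699), cheW, for chemotaxis signalling (2.37, adjusted p = 0.0054), and bll3524 (3.51). The call on cheW was lost without 49 d replicate 3 (1.88) and with the component removed (2.39, adjusted p = 0.0519). In all 100 genes rose and 271 fell. No overlap between the ages was seen for 191 higher and 415 lower of all genes, or 8.16%, where chance gives 2.86%. The total of 371 was 224, 206 and 232 without 49 d replicates 1, 3 and 4 and 200 without 55 d replicate 3. It was 2520 (1098 higher and 1422 lower) with the row-position component removed, which held 23.4% of the variance of this difference, and 348 of those were shared.

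From 55 to 71 d infA, for a translation initiation factor, fell by 2.92 (SE 0.602, adjusted p = 0.00654) and bll3297 by 2.85 (adjusted p = 0.00654). Genes that rose were gpmB, for a phosphoglycerate mutase (2.49, adjusted p = 0.0286), the regulator gene nwsB (2.27, adjusted p = 0.046) and blr6139 (2.67, adjusted p = 0.0173). Each of these 5 calls was lost without 1 of several replicates. That on infA was lost without 55 d replicate 1 (-2.46) or 71 d replicate 2 (-2.56), that on bll3297 without 55 d replicates 2 or 3 or 71 d replicates 1 or 2 (from -2.69 to -2.21), that on blr6139 without 55 d replicate 3 or 71 d replicates 1, 2 or 3 (2.33 to 2.70), that on gpmB without 55 d replicates 1 or 3 or 71 d replicates 2, 3 or 4 (2.10 to 2.86), and that on nwsB without 34 d replicate 3, 55 d replicates 1, 3 or 4 or 71 d replicates 1, 2 or 3 (2.00 to 2.27). In all 25 genes rose and 6 fell. No overlap was seen for 210 higher and 101 lower of all genes, or 4.19%, where chance gives 2.86%. The total of 31 was 4, 67 and 2 without 55 d replicates 1, 2 and 3, and 4, 0, 5 and 55 without 71 d replicates 1 to 4. Where it was 0 by limma, 986 genes had an unadjusted p under 0.05, more than the 1 in 20 of 7426 genes that chance alone gives. The total was 335 (203 higher and 132 lower) with the row-position component removed, which held 55.4% of the variance of this difference, and 20 of those were shared, without gpmB (3.05, adjusted p = 0.0606) and bll3297 (-1.56, adjusted p = 0.0719). In that fit blr6139 was at 0.96 and nwsB at 0.56.

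Genes that fell from 71 to 95 d included hupH at -3.18 (SE 0.602, adjusted p = 0.000182), nifZ, for nitrogenase assembly, at -3.14 and blr2041 at -3.93. Genes that rose were nirK (2.74, adjusted p = 0.0023), hspB (2.72, adjusted p = 0.0023) and bsl7085 (3.79). The call on hspB was lost without 71 d replicate 2 (2.11). In all 15 genes rose and 54 fell. Of all genes, 41 higher and 326 lower had no overlap between the ages, or 4.94%, where chance gives 2.86%. The total of 69 was 43 without 95 d replicate 3 and 43 without 95 d replicate 4. It was 780 (193 higher and 587 lower) with the row-position component removed, which held 37.0% of the variance of this difference, and 64 of those were shared.

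**Figure D2:**
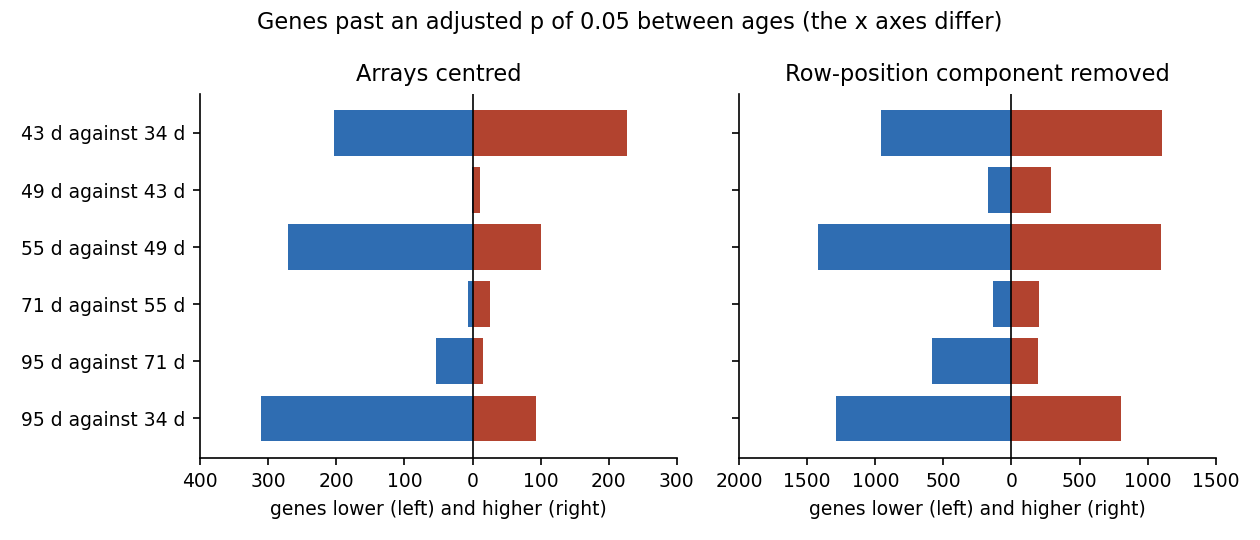
Number of genes past an adjusted p of 0.05 (horizontal axis, lower to the left and higher to the right) for the 5 steps between successive ages and for 95 d against 34 d, as centred (left panel) and with the row-position component removed (right panel, on another scale). As centred the totals run from 12 for 43 to 49 d to 430 for 34 to 43 d.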

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

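The tests of a position effect and of plant age were chosen only after the row-position component had been seen.

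In 57 of 948 groups of 4 replicates, 1 replicate's log2 ratio stood far from the other 3, its gap to the nearest taking up more of the group's range than Dixon's critical value for 4 samples. Chance alone marks about 1 in 20 groups, or 47.4 here. Each value given is that share of the range, for a gene or for the median of a gene list. At 34 d, replicate 2 stood apart by 0.830 for fixK (bll3466) and 0.947 for rplE (bll5388). Replicate 4 did so by 0.972 for the median of exopolysaccharide, 0.926 for groEL (blr5227), 0.862 for groEL (blr5626), 0.960 for phoD (bll7946), 0.966 for pstB (blr1094), 0.970 for nodN (blr3959), 0.859 for cbbL (blr2585) and 0.914 for cbbS (blr2586). At 43 d, replicate 1 stood apart by 0.870 for blr4599, 0.888 for phbB (bll0225) and 0.928 for glgC (blr6458). Replicate 2 did so by 0.858 for atpB (bll1185). Replicate 3 did so by 0.913 for the median of heat shock and chaperones, 0.864 for fixK (bll2109), 0.926 for fixK (bll2757) and 0.855 for fixK (bll3466). Replicate 4 did so by 0.924 for cspA (bsl3986) and 0.848 for nolY (bll2016). At 49 d, replicate 1 stood apart by 0.835 for the median of ribosomal proteins and 0.880 for rpsJ (bll5401). Replicate 2 did so by 0.854 for nifK (blr1744). Replicate 3 did so by 0.923 for mdcE (bll0267), 0.881 for blr2571, 0.832 for bll3524, 0.863 for blr6139, 0.901 for nifN (blr1746), 0.839 for fixB (blr1773) and 0.884 for cbbS (blr2586). Replicate 4 did so by 0.888 for degP (blr5235) and 0.874 for ilvE (bll0229). At 55 d, replicate 1 stood apart by 0.922 for cspA (bsl3986). Replicate 2 did so by 0.836 for the median of exopolysaccharide and 0.898 for ahpC (bll1777). Replicate 3 did so by 0.883 for dctA (blr7187) and 0.873 for bll3524. Replicate 4 did so by 0.875 for cheW (blr2193). At 71 d, replicate 1 stood apart by 0.871 for nirK (blr7089), 0.847 for mntH (bll5044), 0.837 for bll5888, 0.865 for bll6324 and 0.846 for glnA (blr4949). Replicate 2 did so by 0.900 for the median of heat shock and chaperones and 0.832 for nifH (blr1769). Replicate 3 did so by 0.835 for phoD (bll7946). Replicate 4 did so by 0.847 for the median of oxygen and nitrogen-fixation regulators, 0.881 for bll3297, 0.870 for nifN (blr1746), 0.863 for cbbS (blr2586) and 0.892 for shc (blr3004). At 95 d, replicate 1 stood apart by 0.850 for fixK (bll6061), 0.852 for fixN (blr2763) and 0.936 for glnK (blr0612). Replicate 2 did so by 0.874 for blr2571. Replicate 3 did so by 0.942 for phbB (blr3725). Replicate 4 did so by 0.849 for groES (bll2060). The replicates with 1 array, 34 d replicate 4 and 55 d replicate 3, stood apart in 8 and 2 groups.

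For 7 named genes the mean was above 0 at 1 age and below 0 at the compared age, with both means and their difference past the threshold in limma. Single replicates lay on the other side of 0 for rpmJ (43 d replicate 3, -0.21) and bll3297 (71 d replicate 4, 0.24). bll5888 was at -2.07 at 34 d and 1.24 at 43 d (difference 3.30, adjusted p = 7.72e-05, and 1.78 with the row-position component removed). rpmJ (bsl7548) was at -1.71 at 34 d and 1.06 at 43 d (difference 2.78, adjusted p = 0.00113). bll3524 was at -1.71 at 49 d and 1.81 at 55 d (difference 3.51, adjusted p = 2.62e-06). pepA (blr4108) was at 2.62 at 49 d and -1.24 at 55 d (difference -3.86, adjusted p = 1.48e-07). blr6139 was at -1.31 at 55 d and 1.36 at 71 d (difference 2.67, adjusted p = 0.0173, and 0.96 with the row-position component removed), a call lost without 55 d replicate 3 or 71 d replicates 1, 2 or 3 (2.33 to 2.70). bll3297 was at 1.73 at 55 d and -1.12 at 71 d (difference -2.85, adjusted p = 0.00654), a call lost without 55 d replicates 2 or 3 or 71 d replicates 1 or 2 (from -2.69 to -2.21) and with the row-position component removed (-1.56, adjusted p = 0.0719). groES (blr6978) was at 1.12 at 34 d and -1.61 at 95 d (difference -2.73, adjusted p = 0.000369). With the component removed, the means of bll3297 at 71 d (-0.43, adjusted p = 0.307), rpmJ at 43 d (0.80, adjusted p = 0.140) and groES blr6978 at 34 d (0.15, adjusted p = 0.783) were not past the threshold.

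Deviations of single arrays from the row means repeated along the table, with 48.2 rows per turn, and their removal took out 52.6% of the variance between arrays. A row's phase followed that of its 8 neighbouring rows with a mean cosine of 0.914, which an effect of position in the table needs. Genes side by side on the chromosome but over 200 rows apart in the table had a mean cosine of -0.114, which argues against position on the chromosome. Between the 2 arrays of an extract pair, which by their labels share plant age and replicate, the phase turned by a median of 84.3 degrees. That argues against plant age. The phase also turned by a median of 84.8 degrees from one array to the next in the order of the series, within 15 degrees of that in 40 of 45 steps. Array printing, hybridization, the authors' processing or a later alteration of the table may lie behind it. None of these was tested, since scanner files were not used here, so all values as centred hold a component of unknown source. After the removal, ratios to free-living cells may still hold a part of it, through each row's mean over arrays.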

How the results depend on the processing

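Removal of the row-position component, alone or with the replicate block or the estimated correlation, was chosen after the data were seen; the other alternatives were fixed beforehand. Where a count or call changed, the cause was not tested unless fewer arrays, fewer replicates or a stricter threshold entered by construction. Signal over background was not examined, so no limit from dim spots can be given. Of 6135 values of named genes under alternatives, 5829 kept their direction and side of the threshold, 251 kept their direction but no longer passed, 26 newly passed and 29 changed sign. Of the 61 for 95 against 34 d, 29 kept their direction but no longer passed on forward arrays, 21 on dye-swap arrays and 11 without the replicates of 1 array. That number was 7 with quantile normalization, 3 with the dye-term fit and 1 with no centring. Requiring complete values, or values in at least 2 of 4 replicates, moved nothing because every gene was complete, and the fit of only the ages compared has no counterpart for the mean over ages and the F-test. With no centring, the row median, or eBayes with trend and robust, every count stayed within 1.5 times of its value without that change.

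Counts that moved further are given in the order 34, 43, 49, 55, 71 and 95 d against free-living cells, then 95 against 34 d, 43 against 34 d, 49 against 43 d, 55 against 49 d, 71 against 55 d, 95 against 71 d and any age, unless named. Forward arrays alone gave 1427, 1425, 1506, 1209, 1071, 1388, 62, 28, 0, 47, 0, 10 and 228, where by limma 158 and 451 genes had an unadjusted p under 0.05 at the counts of 0. Dye-swap arrays alone gave 1533, 1492, 1511, 787, 1137, 1483, 145, 14, 0, 33, 1, 2 and 250, with 151 genes at an unadjusted p under 0.05 for the 0. Chance alone puts about 1 in 20 of 7426 genes there, more than the 158 and 151 and fewer than the 451. With the row-position component removed the counts were 4830, 4575, 4708, 4502, 4304, 4630, 2091, 2063, 468, 2520, 335, 780 and 4571, and with the replicate block besides they were 4933, 4656, 4783, 4621, 4390, 4708, 2152, 2120, 466, 2568, 353, 814 and 4738. An absolute log2 value of at least 1 left 1958 genes for the mean over ages. An adjusted p under 0.01 left 236, 136, 1, 145, 3, 37 and 708 for the comparisons between ages and any age. Without the replicates of 1 array there were 668 genes for 43 against 34 d, 242 for 55 against 49 d and 2 for 71 against 55 d. For 71 against 55 d there were 62 with quantile normalization, 52 with one median absolute deviation, 9 with the dye-term fit and 6 with only the ages compared in the fit, and for 49 against 43 d 1 with quantile normalization. The estimated correlation left 4 lists for the mean over ages and 2 for 95 against 34 d, and with the component removed 7 and 2.

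Whether replicate numbers pair the samples is not stated in the labels. Of 60 same-numbered pairs of different ages, 45 had deviations correlated above 0.1, and 39 after removal of the row-position component, which itself alternated between replicates 1 and 3 and replicates 2 and 4 (mean r = 0.236). As a hint from the data only, 12 of 24 replicates correlated best with their own number at another age, and 23 after the removal. After it the mean r of deviations was 0.141 for same-numbered replicates of different ages and -0.047 for differently numbered ones. A factor shared by replicate number is therefore not excluded, and the tests without the block leave it in the spread between replicates. The replicate block gave 678 genes for 95 against 34 d, 897 for 43 against 34 d, 31 for 49 against 43 d, 756 for 55 against 49 d, 303 for 71 against 55 d, 152 for 95 against 71 d and 2317 for any age, and it moved no other count by over 1.5 times. For 95 against 34 d it put nifD (-1.72) and groEL blr5626 (-1.58) past the threshold, and it changed no other call on a named gene.

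With 1 replicate left out, counts ran from 181 (without 34 d replicate 3) to 598 (without 34 d replicate 4) for 43 against 34 d, from 2 to 15 for 49 against 43 d (2 without 43 d replicate 3 or 49 d replicate 1), from 200 (without 55 d replicate 3) to 456 for 55 against 49 d, from 0 (without 71 d replicate 2, with 986 genes at an unadjusted p under 0.05 by limma) to 67 (without 55 d replicate 2) for 71 against 55 d, and from 43 (without 95 d replicate 3 or 4) to 87 for 95 against 71 d. The number of lists for 95 against 34 d ran from 4 (without 34 d replicate 2 or 95 d replicate 1) to 7. Other replicates that moved a count by over 1.5 times were 34 d replicate 1 (212), 43 d replicate 1 (201) and 43 d replicate 2 (206) for 43 against 34 d, 43 d replicates 1, 2 and 4 (3, 3 and 6) and 49 d replicates 2, 3 and 4 (4, 6 and 5) for 49 against 43 d, 49 d replicates 1, 3 and 4 (224, 206 and 232) for 55 against 49 d, and 55 d replicates 1 and 3 (4 and 2) and 71 d replicates 1, 3 and 4 (4, 5 and 55) for 71 against 55 d. For every other count the range stayed within 1.5 times.

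Named genes that changed sign were all short of the threshold as centred. For 95 against 34 d, nifH was at 1.93 on forward arrays, 0.83 without the replicates of 1 array, 1.01 with quantile normalization, 0.033 with one median absolute deviation and 0.38 with the dye-term fit, and from -0.54 to 0.83 with 1 replicate left out. The gene nodA was at 0.14 on forward arrays, 1.07 with the component removed, with or without the block, and from -0.33 to 0.20 with 1 replicate left out. For fixK, bll3466 was at -0.0096 on forward arrays, bll2109 at -0.048 with one median absolute deviation and from -0.36 to 0.36 with 1 replicate left out, and bll7696 at 0.088 on dye-swap arrays, 0.064 with the component removed, with or without the block, and from -0.87 to 0.19 with 1 replicate left out. For dctA with the component removed, with or without the block, bll7095 was at 0.17 and blr6145 at -0.22, and blr3723 ran from -0.57 to 0.024 with 1 replicate left out. In the mean over ages dctA blr7187 was at 0.036 on forward arrays and blr4298 ran from -0.15 to 0.011 with 1 replicate left out.

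Lists that changed direction had no adjusted p past the threshold there. In the mean over ages these were polyhydroxybutyrate on forward arrays (adjusted p = 0.976), fix electron transfer and cbb3 oxidase (0.909) and oxygen and nitrogen-fixation regulators (0.99) on dye-swap arrays, other cytochrome oxidases and bc1 (0.877, and 0.87 with an estimated correlation) and the regulators (0.471, and 0.558) with the component removed, and the regulators with the replicate block (0.925). With 1 replicate left out, these 4 lists each ran from 0.959 to 1.00. For 95 against 34 d on forward arrays they were aminoacyl-tRNA synthetases (0.976), the Calvin cycle (0.64), cell division and peptidoglycan (0.976), exopolysaccharide (0.932), other cytochrome oxidases and bc1 (0.777), proteases (0.64) and the tricarboxylic acid cycle (0.64). With the component removed, and then also with an estimated correlation, they were amino acid biosynthesis (0.948 and 0.951), aminoacyl-tRNA synthetases (0.932 and 0.927), cell division and peptidoglycan (0.717 and 0.716) and other cytochrome oxidases and bc1 (0.546 and 0.548). With 1 replicate left out the adjusted p ran from 0.896 to 0.995 for amino acid biosynthesis, 0.686 to 0.993 for the Calvin cycle, 0.443 to 0.995 for cell division and peptidoglycan, 0.884 to 0.989 for exopolysaccharide, 0.766 to 0.993 for iron uptake and heme, 0.666 to 0.995 for other cytochrome oxidases and bc1, 0.666 to 0.989 for oxygen and nitrogen-fixation regulators, 0.752 to 0.989 for proteases and 0.862 to 0.993 for the tricarboxylic acid cycle.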

Other observations

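The pst, pho, phn, cyc and cytochrome P450 gene groups were chosen after their values were seen, as were the tests on the nod-nif window; the other tests of the patterns, and the counts of other splits, were fixed before their results.

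The genes of the phosphate transporter were higher in bacteroids than in free-living cells and lower at 95 d than at 34 d, as single genes, since these groups had no test as a set. Over 24 replicates (SE 0.174), 4 of 4 pst genes were higher than in free-living cells, pstS at 3.45, pstB at 2.74, pstC at 2.17 and pstA at 1.67. Of 8 pho genes 7 were higher, with phoD at 4.99 and phoU at 2.79, and phoH was lower, at -1.66. Between 34 and 95 d 4 of 4 pst genes fell, with a median of -2.38 (limma, SE 0.602, n = 4 and 4) and of -2.34 with the row-position component removed. The call on pstS (-1.94) was lost without 34 d replicates 3 or 4 or 95 d replicates 1 or 3 (from -1.94 to -1.43), and that on pstA (-2.03) without 34 d replicate 4 (-1.83) or 95 d replicate 4 (-1.66). In the same comparison phoD (-3.38), phoU (-2.92) and phoE (-2.48) fell and the other 5 of 8 pho genes did not pass, with 6 of 8 lower once the component was removed. Of 7 phn genes, for phosphonate use, 6 were higher in bacteroids, with a median of 0.84, the call on phnH (0.38) being lost without 34 d replicates 2 or 3, 43 d replicates 1 or 3, 49 d replicates 2 or 3, 55 d replicates 2 or 4, 71 d replicates 3 or 4 or 95 d replicates 1 or 3 (0.32 to 0.38). Between 34 and 95 d 0 of these 7 passed in limma and 4 had an unadjusted p under 0.05, and the median of the 7 was 0.82 as centred and 0.089 with the component removed.

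Of 10 cyc genes, for cytochromes c and their assembly, 8 were lower in bacteroids, with a median of -1.48 and cycA at -3.13. All 3 cytochrome P450 genes were higher, with a median of 4.78, and CYP117 was at 1.98. Between 34 and 95 d 2 of these 3 fell, CYP117 at -2.72 and CYP114 at -1.88, the latter not past the threshold with the row-position component removed (-1.38, adjusted p = 0.0533), nor without any 1 of the 4 replicates at 34 d or 95 d replicates 1, 3 or 4 (from -1.99 to -1.64). The third, CYP112, was at -1.77 (adjusted p = 0.0562), and passed with the component removed (-1.95, adjusted p = 9.96e-05).

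The steps from 34 to 43 d and from 49 to 55 d ran against each other across 7426 genes, which are not independent (r = -0.331). As centred 35 genes rose and then fell where independent lists would share 8.28 and 10 fell and then rose against 2.73, but 20 fell in both steps against 7.41 and 0 rose in both against 3.06; with the row-position component removed these were 456 against 212, 343 against 142, 152 against 183 and 43 against 164. Removal of the component left r = -0.313, which met the bound of -0.3 set beforehand against the component. Leaving out each of 16 replicates gave -0.328 to -0.277, which in part falls short of that bound. None of these lost the negative correlation. With the bound met only in part, the test cannot tell how far the component is its source. Other free-living cultures behind the arrays at 43 and 49 d cannot be told apart from a change in the bacteroids, since each array gives only their ratio. The spread of the shift in the 300 genes of lowest mean ratio was 0.799 times that in the 300 of highest (SD 0.666 and 0.834). This lies between the bounds set for either reading. A changed reference can also move genes at any mean ratio, so that spread does not decide. Plant age stays open as an untested biological explanation.

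The nod-nif window was lower at 95 d than at 34 d. Its median was -0.58 with the row-position component removed, against -0.56 as centred. The component repeats about every 48 rows and the longer runs of the window hold 166 and 264. It largely evens out there, so its removal could hardly move the median and is no test of it as the cause. The rows are sorted by locus tag, so the window lies in 4 separate runs of them, with medians of -0.66, -0.57, -0.45 and -0.53 for bll, blr, bsl and bsr tags. Other stretches of as many rows reached at most -0.19 and -0.15 for the runs of 166 and 264 rows, which argues against a drift along neighbouring rows there, but -0.46 and -0.63 for those of 35 and 54, where it stays open. That symbiosis genes were transcribed less in the oldest bacteroids is a hypothesis drawn from the same data on which no test here bears directly, and a change in the make-up of the nodule population may also lie behind the fall and was not tested.

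Other splits of the same replicates bear on whether chance could give such counts. Over 100 sign patterns of the replicates the 4754 genes of the mean over ages, and over 100 regroupings the 1306 genes of any age, were reached by 1, the real one, and the highest other counts were 914 and 140. Of 35 splits only 1, the real one, gave as many genes between ages. The counts were 404 genes against a highest other of 34 for 95 against 34 d, 430 against 76 for 43 against 34 d and 12 against 2 for 49 against 43 d. They were 371 against 34 for 55 against 49 d, 31 against 21 for 71 against 55 d and 69 against 5 for 95 against 71 d. This is the smallest share that 35 splits allow, and it is under 0.05 for each comparison taken alone. With a correction over the 6 comparisons 35 splits are too few to exclude chance. For 71 against 55 d the count was 0 by limma without 71 d replicate 2, with 986 genes at an unadjusted p under 0.05. For single ages the 8 sign patterns are too few for a share under 0.05, with real counts of 2542, 2397, 2538, 2156, 2036 and 2458 and highest other counts of 340, 0, 0, 173, 8 and 0. For the lists chance is not excluded. The 8 lists of the mean over ages were reached by 15 of 100 sign patterns (highest other 13, median of the others 3). The 7 lists of 95 against 34 d were reached by 2 of 35 splits (highest other 7, median of the others 2).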
